A study of Homo sapiens with 6 samples.

How the data were processed

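RNA was sequenced from 6 samples of the MDA-MB-231 breast cancer line, 3 wild-type controls and 3 SNHG14 knockdown samples, grouped by the genotype given in the labels. Per the labels' protocols, RNA was extracted with trizol, ribosomal RNA was removed and libraries were built with a low-input RNA kit. Whether the kit or the counting kept strand, and the genome build and annotation, were not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR. The deposited table gives whole-number counts per gene, raw and not normalized per the file headers, for 15915 protein-coding genes. A second block of 6 columns, values the authors normalized with edgeR per the file headers, was not used here. Of the table's genes, 41 rows carried a repeated symbol and 13 symbols had been turned into calendar dates, so genes were handled by Ensembl ID. Current symbols were looked up by ID for 15508 of the 15915 genes. Chromosomes and strands come from GENCODE release 29.

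Genes with too few counts were removed with filterByExpr by group, which kept 12230. Libraries were scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F-test, group as the only term, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are counts scaled by TMM library size with edgeR's cpm function. At these depths 1 count equals 0.0320 to 0.0382 CPM. Standard errors rest on 3 libraries per group, whose biological coefficient of variation was 0.222. Intervals in the closing section come from 1000 bootstrap draws of genes or list members, not of libraries. They hold no spread between libraries and treat genes as independent.

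Gene lists, 35 in all, were fixed before the data were examined, as were the groups, the tests, most alternatives and the rule for named genes. The 31 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the lists. The same lists were tested with an estimated correlation and with fry. With an estimated correlation 0 of the 7 calls held. Directions and shifts per library are medians over list members of the difference from the mean of the controls. SNHG14 was to be named first, and its level was not analysed here. Other named genes were the 12 largest changes per direction among genes that passed with a group mean of at least 5 CPM and no overlap between groups, and the 5 smallest p-values per direction. Where fewer than 5 passed, as happened in both directions, the 5 with the smallest unadjusted p at that level were named instead. From lists that were not called, the members of highest level could be named. Further list members were chosen by small p after their values were seen; they include HMGCS1's pathway genes, cytokines, SLC7A11, ETS1, ID1, FADS2, KLF6, MKRN3, TUBGCP5 and FBN1. Some genes that these rules select are not reported here.

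The gene test was tested on simulated counts for the same comparison, drawn from the real means and depths with 200 genes changed. Among 12132 genes it recovered 6 of 50 changed 1.5-fold, 33 of 50 changed 2-fold, and 50 of 50 changed 4-fold or 8-fold, with 8 false calls. In a simulation with 12107 genes and 1 shifted list, camera called that list and 0 of the others. A simulated blend of libraries with a share of 0.30 returned 0.30 over 10912 genes. Simulated libraries vary gene by gene, whereas the real ones also deviate together. The simulated recovery thus does not carry over, and a 4-fold change need not pass in the real comparison. ATF3, 16.5-fold higher on knockdown, did not pass there (adjusted p = 0.177 in edgeR's quasi-likelihood test).

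Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and Wald test, limma-voom, no filter and a filter of 5 CPM in 3 samples, the replicate number as a block, each sample left out, an adjusted p below 0.01, and 1 row per symbol. Alternatives added after the data were seen were edgeR's exact test, a robust quasi-likelihood fit, limma-voom with sample quality weights, and knockdown replicate 2 alone against the controls. Transcript length and GC content were those of each gene's longest GENCODE 29 transcript. Distribution over chromosomes was not tested with 1 called gene, and biotypes were not compared because every row was protein-coding. No comparison by the authors was used here.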

Results

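Gene expression was measured by RNA sequencing in MDA-MB-231, a human triple-negative breast cancer cell line. Triple-negative tumours lack the oestrogen and progesterone receptors and HER2. The question named in the study's title was which genes respond when SNHG14, a long noncoding RNA that hosts small nucleolar RNAs, is depleted. The samples formed 2 groups, 3 wild-type control samples and 3 SNHG14 knockdown samples. Gene counts summed to 26553852, 26211514 and 27980511 in control replicates 1, 2 and 3, and to 27353991, 31207707 and 28681651 in knockdown replicates 1, 2 and 3. Levels are given as CPM, counts scaled to a common library size. Between 13883 and 14529 of the 15915 listed genes had at least 1 count in a library. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

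The libraries of a group were not equally alike. Control replicates 2 and 3 were the closest pair, with a Spearman correlation of 0.997 across the 12230 genes tested, where genes are not independent replicates. Knockdown replicates 1 and 2 were the least alike, at 0.954. Control replicate 1 correlated with knockdown replicate 2 at 0.9922, and with control replicates 2 and 3 at 0.9905 and 0.9909. The first principal component held 54.4% of the variance and set knockdown replicate 1 apart, with knockdown replicate 3 between knockdown replicates 1 and 2. A linear blend of 46% knockdown replicate 1 and 54% knockdown replicate 2 lay 2.03 times sampling variance from knockdown replicate 3, closer than any pair of libraries. No pair of libraries agreed within sampling noise: the closest pair differed by 5.89 times the variance that counting alone gives, as a median over 10912 genes.

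**Figure D1:**
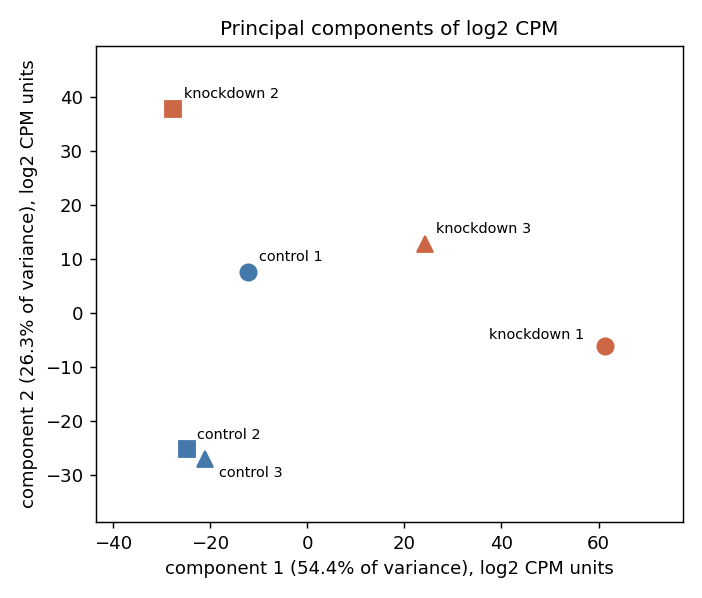
Principal components of log2 CPM over 12230 genes, 1 point per library; component 1 (54.4% of the variance) is on the x axis and component 2 (26.3%) on the y axis, both in log2 units. Knockdown replicate 1 lies at 61.3 on component 1, knockdown replicate 3 at 24.3 and knockdown replicate 2 at -27.5, near control replicates 2 and 3 (-24.8 and -21.1) on that component only; on component 2 they lie at 37.8, -25.2 and -27.

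The level of SNHG14 itself was not analysed here, so the depletion was not checked in these libraries. Of the genes around its locus on chromosome 15, 7 were tested. UBE3A, a ubiquitin ligase gene on the opposite strand that SNHG14 overlaps in GENCODE release 29, was higher in all 3 knockdown libraries (199, 185 and 188 CPM) than in all 3 controls (163, 148 and 163 CPM). Its log2 fold change of 0.27 (SE 0.10) did not pass edgeR's quasi-likelihood test (adjusted p = 0.265). Whether the counting used strand was not given in the sources used here, so reads from UBE3A and from its antisense partner cannot be told apart in this value. The neighbours as a list had a median log2 fold change of -0.08, and 0 of the 7 passed when adjusted over the list alone. Fry's mixed test, which counts changes in either direction, called the list (adjusted p = 0.0291). Fry's directional test did not (adjusted p = 0.642). MKRN3 (log2 fold change -1.27, SE 0.37, edgeR adjusted p = 0.227), at 3.49 CPM or less in each library, and TUBGCP5 (-0.36, SE 0.16) were lower in all 3 knockdown libraries than in all 3 controls. HERC2 had a log2 fold change of -0.14 (SE 0.10) and CYFIP1 of 0.08 (SE 0.12).

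SNHG14 knockdown was compared with control gene by gene. FOSB, which encodes a subunit of the AP-1 transcription factor, rose 7.2-fold on knockdown, from 7.48 ± 0.60 to 53.9 ± 14.5 CPM (mean ± SD, n = 3 each). Its log2 fold change was 2.85 (SE 0.22), with an adjusted p of 0.023 in edgeR's quasi-likelihood test. FOSB, ENSG00000125740 on chromosome 19, was the 1 gene of 12230 that passed, and it also passed 2-fold. With edgeR's test 1 gene was higher and 0 were lower, while 2043 genes had an unadjusted p under 0.05, of which 1046 were higher and 997 lower. The count depended strongly on the tool: DESeq2's Wald test called 294 genes higher and 237 lower, and limma-voom called 0. Every library of one group lay above every library of the other for 2756 genes, or 22.5% of those tested. Chance gives 10% only if all 6 libraries are separate observations. If knockdown replicate 3 is a blend of replicates 1 and 2, the chance share is higher, so 22.5% cannot be called an excess. FOSB's call was lost without control replicate 1, 2 or 3 (adjusted p = 0.0663, 0.481 and 0.388 in edgeR's test) and without knockdown replicate 3 (0.119). It held without knockdown replicate 1 (0.000615) and without knockdown replicate 2 (6.29e-06). Both of these fits kept knockdown replicate 3, which lay near a blend of replicates 1 and 2. The knockdown libraries left then correlated at 0.9864 and 0.9873, against 0.9544 for replicates 1 and 2. Their spread may thus be too small, which also limits the counts that follow. Without knockdown replicate 2 edgeR called 1091 genes higher and 627 lower, and without knockdown replicate 1 it called 6 higher.

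The other genes with the smallest p-values missed the threshold in edgeR's quasi-likelihood test. NR4A2, an orphan nuclear receptor gene, averaged 4.01 ± 0.38 CPM in control and 14.6 ± 1.91 in knockdown (n = 3 each), a log2 fold change of 1.86 (SE 0.19, edgeR adjusted p = 0.0809). The remaining 7 named genes had an adjusted p of 0.177 each in the same edgeR test. NFKBIZ, an atypical NF-kB inhibitor family gene, averaged 114.9 ± 7.92 CPM in control and 293 ± 73.3 in knockdown, a log2 fold change of 1.35 (SE 0.19). ATF3, a stress-induced transcription factor gene, averaged 2.22 ± 1.59 and 36.5 ± 16.8 CPM, a log2 fold change of 4.04 (SE 0.57). On the lower side, HMGCS1, which makes HMG-CoA for the mevalonate pathway, averaged 220 ± 51.2 CPM in control and 91.6 ± 5.34 in knockdown, a log2 fold change of -1.26 (SE 0.18). METTL3, the catalytic subunit of the mRNA m6A methyltransferase, averaged 76.8 ± 9.70 and 41.7 ± 3.13 CPM, a log2 fold change of -0.88 (SE 0.13). The zinc finger genes ZNF93 and ZNF519 had log2 fold changes of -0.94 (SE 0.13) and -1.14 (SE 0.18). SYNM, an intermediate filament gene, had a log2 fold change of -0.95 (SE 0.15). In all 9 genes named here, FOSB included, the groups did not overlap.

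**Figure D2:**
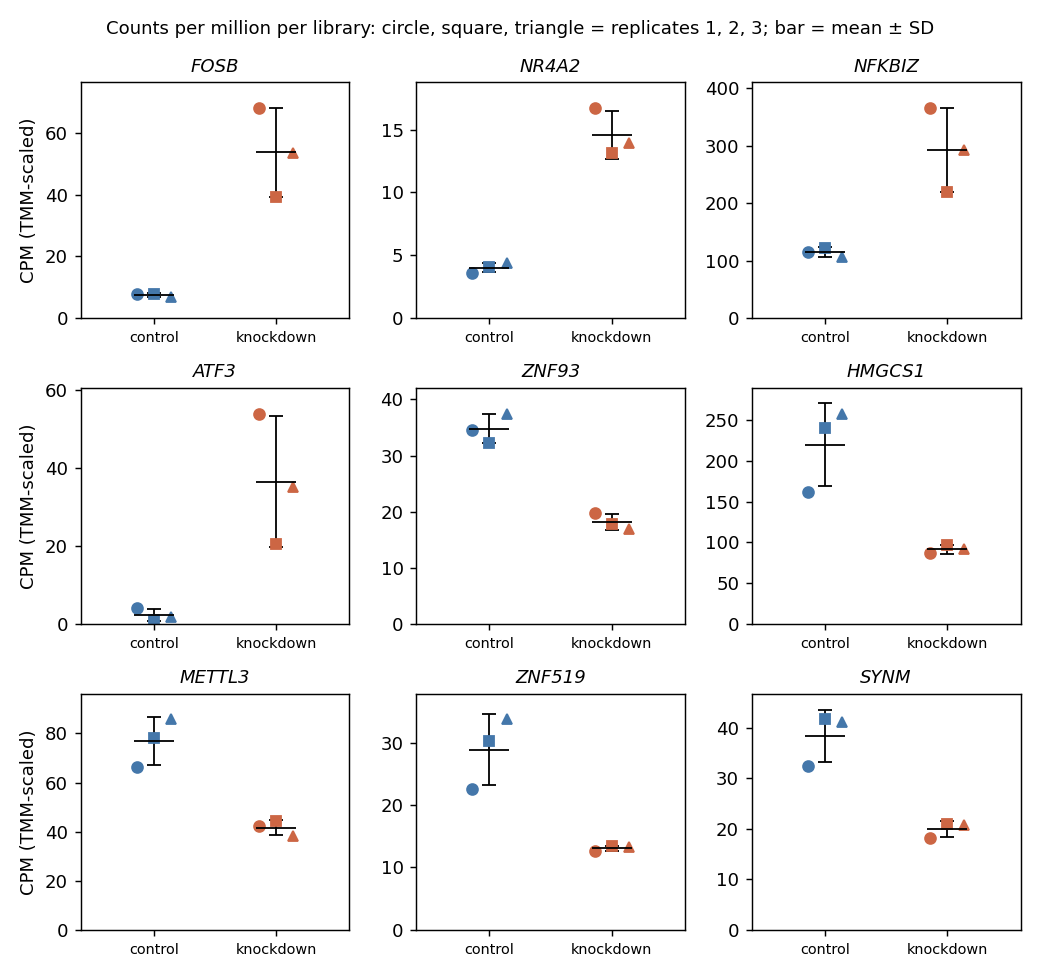
CPM per library for the 9 named genes, 1 panel per gene with its own y axis starting at 0; circles, squares and triangles are replicates 1, 2 and 3, and black bars give the mean ± SD (n = 3). FOSB lies between 6.79 and 7.91 CPM in the controls and between 39.4 and 68.4 CPM in the knockdown libraries.

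Among the immediate-early and AP-1 genes, which are transcribed within minutes of a stimulus, 25 of 33 tested members had a positive fold change. In edgeR's test 1 passed over all genes (FOSB), while adjusted over the list alone 11 passed as higher and 1 as lower. FOS, the founding AP-1 subunit gene, lay above every control (36.4, 64.5 and 53.9 CPM) in every knockdown library, with a log2 fold change of 1.44 (SE 0.22, adjusted p = 0.177 in edgeR's test). The list's median log2 fold change was 0.43, and camera called the list higher (adjusted p = 3.41e-06). The adjusted p was 0.715 with an estimated correlation. Without knockdown replicate 1 the median was 0.24 (camera adjusted p = 0.000416). With knockdown replicate 2 alone, an alternative chosen after the data were seen, the call was lost (median 0.11, camera adjusted p = 0.161). Relative to the control mean, the median member stood at 0.78, 0.11 and 0.44 log2 units in knockdown replicates 1, 2 and 3. Not all members went with the list: KLF6, the 1 that passed as lower over the list alone, had a log2 fold change of -0.71 (SE 0.19).

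The ATF4 and integrated stress response list, genes induced when amino acids are scarce or translation initiation is impaired, had a positive fold change for 36 of 36 tested members. In edgeR's test 0 passed over all genes, and 27 passed as higher adjusted over the list alone. The median log2 fold change was 0.95, and camera called the list higher (adjusted p = 3.46e-12). The adjusted p was 0.763 with an estimated correlation. Without knockdown replicate 1 the median was 0.60 (camera adjusted p = 5.39e-08). With knockdown replicate 2 alone, chosen after the data were seen, the call was lost (median 0.10, camera adjusted p = 0.264). The size differed greatly by library: the median member stood at 1.47, 0.10 and 0.95 log2 units above the control mean in knockdown replicates 1, 2 and 3, and at 0.00, 0.02 and -0.03 in the controls. SLC7A11, the cystine importer, was at 857, 420 and 636 CPM in the knockdown libraries and 251, 119 and 138 CPM in the controls. ATF4 itself was at 400, 259 and 338 CPM against 179, 203 and 186 CPM. MTHFD2, a mitochondrial folate enzyme gene, had a log2 fold change of 0.97 (SE 0.21, adjusted p = 0.205 in edgeR's test). ATF3 belongs to both this list and the immediate-early list.

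NF-kB targets and inflammatory cytokines stood highest in knockdown replicate 1 and next highest in knockdown replicate 3. Of 28 tested members 23 had a positive fold change, with 0 passing over all genes in edgeR's test. Adjusted over the list alone, 8 passed as higher and 1 as lower. Camera called the list higher (median log2 fold change 0.45, adjusted p = 0.00521), and the adjusted p was 0.892 with an estimated correlation. The call was lost without knockdown replicate 1 (median 0.13, camera adjusted p = 0.288), and without knockdown replicate 2 the median was 0.70. The median member stood at 0.96, -0.19 and 0.37 log2 units in knockdown replicates 1, 2 and 3. IL1A, the cytokine interleukin-1 alpha, was at 446, 11.4 and 222 CPM in those libraries and between 8.62 and 14.6 CPM in the controls. IL8, a neutrophil chemokine, was at 367, 48.6 and 205 CPM against 36.8 to 40.5 CPM. PTX3, a secreted pattern recognition protein gene, was at 394, 213 and 305 CPM against 139 to 145 CPM.

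Genes of cholesterol synthesis stood lower in each knockdown library. Of 25 tested members 24 had a negative fold change, and the groups did not overlap for 16. In edgeR's test 0 passed over all genes, and 14 passed as lower adjusted over the list alone. Camera called the list lower (median log2 fold change -0.71, adjusted p = 2.7e-11). The adjusted p was 0.615 with an estimated correlation. The median member stood at -0.96, -0.54 and -0.69 log2 units in knockdown replicates 1, 2 and 3, and at -0.22, 0.14 and 0.10 in control replicates 1, 2 and 3. FDPS, farnesyl diphosphate synthase, was at 143, 216 and 180 CPM in the knockdown libraries and 250, 351 and 351 CPM in the controls. MVD, mevalonate diphosphate decarboxylase, was at 13.2, 16.4 and 14 CPM against 23.6, 29.9 and 29.4 CPM. Fatty acid synthesis and desaturation was not called by camera (median log2 fold change -0.13, adjusted p = 0.235), and 2 of its 23 members passed as lower adjusted over the list alone. FADS2, a fatty acid desaturase gene, was at 237, 211 and 224 CPM against 297, 341 and 319 CPM.

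The list of NRF2, glutathione and ferroptosis genes, which hold antioxidant and iron storage functions, had a similar median in every knockdown library, at 0.20, 0.22 and 0.24 log2 units. Camera called it higher (median log2 fold change 0.24, adjusted p = 0.00894), and the adjusted p was 0.615 with an estimated correlation. The call was lost without knockdown replicate 2 (median 0.21, camera adjusted p = 0.0585). Of 31 members 22 had a positive fold change. In edgeR's test 0 passed over all genes, and 1, SLC7A11, passed adjusted over the list alone. SLC7A11 also belongs to the ATF4 and integrated stress response list, so its pass is not separate from that list's result. FTH1, ferritin heavy chain, was at 1870, 1521 and 1683 CPM in the knockdown libraries and 1437, 1220 and 1125 CPM in the controls. TXNRD1, thioredoxin reductase, was at 1140, 890 and 1009 CPM against 792, 571 and 571 CPM.

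Genes of the G1/S transition and DNA replication had a negative fold change for 40 of 42 members, with the largest shift in knockdown replicate 1. The median member stood at -1, 0.14 and -0.29 log2 units in knockdown replicates 1, 2 and 3. MCM3, a subunit of the replicative helicase, was at 248, 557 and 425 CPM in those libraries and between 526 and 536 CPM in the controls. In edgeR's test 0 members passed over all genes and 0 adjusted over the list alone. Camera called the list lower (median log2 fold change -0.31, adjusted p = 0.000218), and the adjusted p was 0.892 with an estimated correlation. The call was lost without knockdown replicate 1 (median -0.06, camera adjusted p = 0.511), and without knockdown replicate 2 the median was -0.63. Nuclear respiratory chain subunits were also called lower by camera (60 of 75 members negative, median log2 fold change -0.15, adjusted p = 0.00521). The adjusted p was 0.892 with an estimated correlation, and the median member stood at -0.35, 0.07 and -0.15 log2 units by library. This call too was lost without knockdown replicate 1 (median -0.05, camera adjusted p = 0.549), and without knockdown replicate 2 the median was -0.29. Of these subunits 0 passed in edgeR's test over all genes, and 0 adjusted over the list alone. Without knockdown replicates 1 and 3, an alternative chosen after the data were seen, camera called the replication list higher (0.14), the reverse of its direction over all libraries. The medians for NF-kB targets (-0.19) and the respiratory chain (0.07) also changed sign then.

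**Figure D3:**
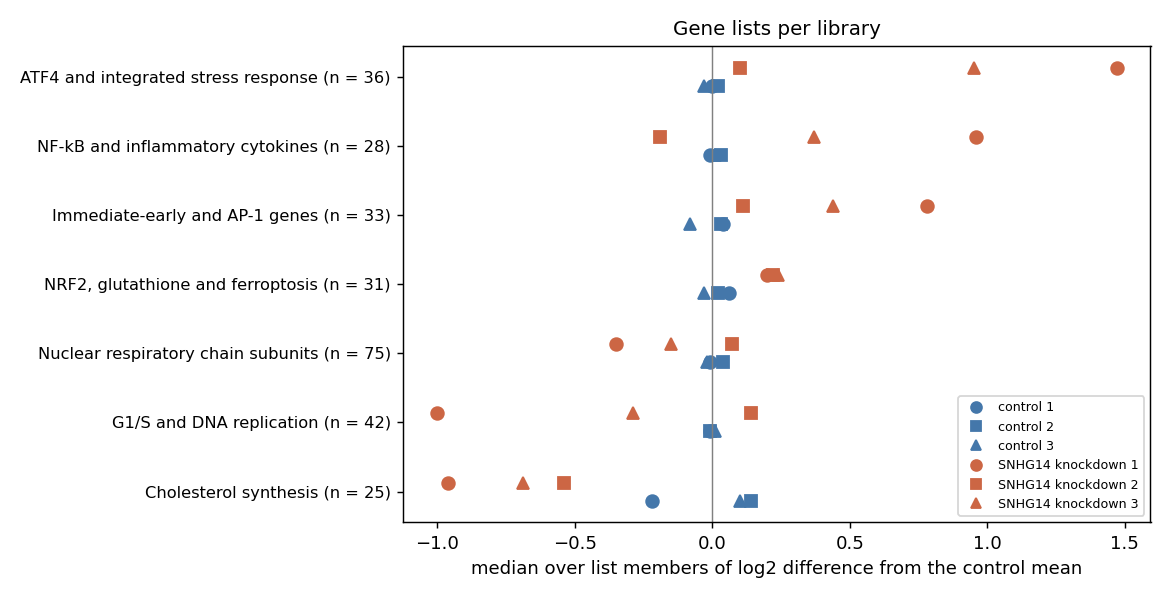
Median over list members of the log2 difference from the control mean, on the x axis, for the 7 lists called by camera; 1 point per library, with the number of members tested beside each list. Stress response genes lie at 1.47 in knockdown replicate 1 and at 0.10 in knockdown replicate 2, while cholesterol synthesis lies between -0.96 and -0.54 in all 3 knockdown libraries.

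The other 24 of the 31 lists tested were not called by camera over all 6 libraries. Among genes tied to invasion, the median log2 fold change was 0.10 for mesenchymal genes, 0.17 for TGF-beta targets, 0.19 for YAP/TAZ targets and 0.16 for extracellular proteases and inhibitors. VIM, vimentin, had a log2 fold change of -0.66 (SE 0.22). In these lists 3 mesenchymal genes, 2 TGF-beta targets and 3 protease genes passed as higher adjusted over the list alone in edgeR's test, and 1 TGF-beta target, ID1, as lower. Epithelial genes had a median of 0.17, where the test's direction was down and the mean 0.12, and basal breast cancer genes one of 0.20, with 1 gene, ETS1, higher adjusted over the list alone. Interferon-stimulated genes had a median of -0.06, with 22 of 37 members negative and 13 of them at an unadjusted p under 0.05 (camera adjusted p = 0.0961). With no filter on low counts camera called the interferon list lower (adjusted p = 0.0472), as it did in 4 of the 6 fits that left out 1 library (camera adjusted p from 0.0136 to 0.0447). Without knockdown replicate 1 camera called YAP/TAZ targets higher (adjusted p = 0.0411), and without knockdown replicate 2 the protease list (0.00623). These calls used the preset correlation. With an estimated correlation over all 6 libraries, camera's adjusted p was 0.715 for interferon genes and YAP/TAZ targets and 0.892 for proteases. Adjusted over the list alone, 0 interferon-stimulated genes passed in edgeR's test, nor did any epithelial gene or YAP/TAZ target.

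Cell cycle and growth lists followed the split between libraries. Knockdown replicate 2 alone was fitted after the data were seen, with camera's preset correlation. Camera then called G2/M, heat shock, ribosomal protein, ribosome biogenesis and splicing lists higher, and hypoxia, epithelial and interferon lists lower. Those calls rest on 1 knockdown library. Without knockdown replicate 2 camera called G2/M and heat shock lists lower instead. Neither fit was run with an estimated correlation, with which 0 lists were called over all libraries. G2/M and mitosis genes had a median log2 fold change of -0.07, with -0.39, 0.22 and -0.06 in knockdown replicates 1, 2 and 3. Heat shock proteins had a median of -0.17, with -0.73, 0.23 and -0.15 by library. HSPA8, the constitutive Hsc70 chaperone, was at 818, 4722 and 2830 CPM in the knockdown libraries and 2833 to 3350 CPM in the controls. Cytosolic ribosomal proteins (median 0.05) and MYC and ribosome biogenesis genes (median 0.01) stood at -0.22, 0.29 and 0.06, and at -0.33, 0.34 and 0.02 by library. RNA processing and splicing factors had a median of -0.05, and the nuclear paraspeckle list one of 0.04, where the test's direction was down and the mean -0.06. Replication-dependent histones had a median of -0.06, mitochondrially encoded genes -0.26, hypoxia and glycolysis -0.05 and apoptosis regulators -0.05. The unfolded protein response of the endoplasmic reticulum had a median of -0.07 and a mean of 0.03, p53 targets a median of 0.02, and autophagy and lysosome 0.01, where the test's direction was down. For these 13 lists 0 members passed in edgeR's test, over all genes or adjusted over the list alone. The 3 tested snoRNA host genes had a median of -0.19 and were too few for camera.

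Genes of cell types other than the cultured line were measured to see what other cells the samples could hold. Luminal breast genes had a median log2 fold change of -0.13 and a mean of 0.09 over 14 members, and endothelial genes a median of 0.14 over 5. Fibroblast genes had a median of 0.72 over 4 tested members, too few for camera, in which 2 passed as higher and 1 as lower adjusted over the list alone in edgeR's test. Of these FBN1, fibrillin, was at 100, 80.5 and 87.7 CPM in knockdown and 64.4 to 71.8 CPM in control. The 13 listed leukocyte genes summed to 3.62 CPM or less in each library, and 2 were tested, with a median of 0.78. With no filter on low counts camera called the leukocyte list higher (adjusted p = 0.0179), at those levels. The 2 tested erythroid genes had a median of -0.85, and HBB was highest in control replicate 2, at 11.9 CPM.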

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

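Tests chosen only after the data were seen are edgeR's exact test, the robust fit, sample quality weights and knockdown replicate 2 alone. The main count was 1 gene changed, 1 higher, 0 lower and 1 at least 2-fold. DESeq2's size factors, the stricter filter, 1 row per symbol and the robust fit gave the same counts. DESeq2's Wald test gave 531 changed (294 higher, 237 lower, 183 at least 2-fold). The exact test gave 335 (172, 163 and 166), of which 313 were among DESeq2's calls. Quality weights gave 6068 (3044, 3024 and 810), with a weight of 14.72 for knockdown replicate 3 and 0.26 for knockdown replicates 1 and 2. These weights grow as a library nears its group mean. Knockdown replicate 3 lay near an even blend of replicates 1 and 2, so the 6068 calls cannot be read as those of a more sensitive test. Limma-voom gave 0 changed, 0 higher and 0 at least 2-fold, as did an adjusted p below 0.01. No filter gave 2 changed, 2 higher and 2 at least 2-fold (FOSB and NR4A2). Leaving out 1 library gave 0 to 1718 changed, 0 to 1091 higher, 0 to 627 lower and 0 to 650 at least 2-fold. The maximum came without knockdown replicate 2, which left knockdown replicates 1 and 3, a closer pair than replicates 1 and 2. Without control replicate 1 the 1 call was COL8A1, named after its values were seen, not FOSB. Knockdown replicate 2 alone gave 6 changed, 3 higher (FOSB, EGR1, ADAMTS1), 3 lower (ASB2, ZNF112, VEGFA) and 6 at least 2-fold, with that lone sample assumed to vary like the controls.

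With the replicate block 1 gene passed, ATF3 in place of FOSB, whose log2 fold change was 2.82 (edgeR adjusted p = 0.0994; range over alternatives 2.2e-29 to 0.481). Same-numbered libraries correlated at -0.035, 0.044 and -0.027 in their deviations, so numbers did not pair samples. FOSB's log2 fold change lay between 2.40 and 3.01 in all 18 alternatives, and it passed in 11. The other 8 named genes kept their direction in all 18. For FOSB and these genes that was close to fixed in advance, because their groups did not overlap and every fit used these same libraries.

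Lists called went from 7 to 0 with an estimated correlation, 0 with fry and 11 with knockdown replicate 2 alone. No filter gave 9, adding interferon-stimulated genes lower and leukocyte genes higher. Leaving out 1 library gave 8 or 9, but not always the 7: replication, NF-kB and respiratory chain calls were lost without knockdown replicate 1, and the NRF2 call without knockdown replicate 2. Added were interferon genes lower without control replicate 1 or 3 or knockdown replicate 1 or 3, ribosomal proteins higher without control replicate 2 or knockdown replicate 1, ribosome biogenesis and YAP/TAZ genes higher without knockdown replicate 1, and, without knockdown replicate 2, proteases higher and G2/M and heat shock genes lower. With knockdown replicate 2 alone only the cholesterol and NRF2 calls held. Replication was called higher (0.14), as were G2/M, heat shock, ribosome biogenesis, ribosomal protein and splicing genes, and epithelial, interferon and hypoxia genes were called lower; the stress response (0.10), immediate-early (0.11), NF-kB (-0.19) and respiratory chain (0.07) calls were lost, the last 2 with reversed medians. The cholesterol list's median stayed between -0.85 and -0.55. Except where fewer samples were fitted, or a stricter threshold, the cause was not tested. Lists were not rerun under the other gene tests, which camera does not use. Alternatives for normalized values, the SNHG14 level, chromosomes, biotypes and the authors' comparison were not run. Depth was not varied; 1 count equals 0.0320 to 0.0382 CPM.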

Other observations

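Genes in this paragraph were chosen after their values were seen. IFIT1, IFIT2 and IFIT3, which are interferon-induced, stood lower in control replicate 1 than in the other controls; IFIT5 did not (39.6, 36.9 and 37.8 CPM in control replicates 1, 2 and 3, and 40.9, 46.3 and 40.1 CPM in knockdown replicates 1, 2 and 3). IFIT1 was at 30.3 CPM in control replicate 1 and at 111 and 106 CPM in control replicates 2 and 3, against 11.1, 27.7 and 18.5 CPM in knockdown replicates 1, 2 and 3. IFIT3 was at 80.5, 180 and 194 CPM in the controls and 61.5, 78.2 and 68.4 CPM in the knockdown libraries. TXNIP, a glucose-responsive arrestin gene, was at 1390 CPM in knockdown replicate 1, 94.1 in replicate 2, 728 in replicate 3 and 93.9 to 100 in the controls. ASNS, asparagine synthetase, was at 568, 21.5 and 271 CPM in knockdown replicates 1, 2 and 3 and 27.3 to 31.7 CPM in the controls. RRM2, a ribonucleotide reductase subunit, was at 78.8, 435 and 257 CPM against 251 to 283 CPM. EGR1, an immediate-early gene, was at 336, 64.8 and 188 CPM against 18.1 to 19.7 CPM.

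In the pathway annotation of the deposited table, camera with the preset correlation called 2 of 249 sets, both lower: terpenoid backbone biosynthesis (adjusted p = 0.00254) and steroid biosynthesis (adjusted p = 0.0081). Of 1109 biological process terms, 2 were called lower, cholesterol biosynthesis (adjusted p = 3.36e-05) and isoprenoid biosynthesis (adjusted p = 0.00606). None of the sets was called with an estimated correlation (lowest camera adjusted p = 0.901 and 0.999). Among 430 genes with ZNF symbols, 254 had a negative fold change, with 77 lower and 19 higher at an unadjusted p under 0.05 in edgeR's test; their medians were 0.02, -0.29 and -0.09 in knockdown replicates 1, 2 and 3 and -0.09, 0.02 and 0.09 in the controls, so only knockdown replicate 2 lay outside the control range. No set test was run on them.

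Of the tests that follow, those of scatter around the blend and of UBE3A were chosen only after their results had been seen. Knockdown replicate 3 lay between knockdown replicates 1 and 2. A blend of 46% replicate 1 and 54% replicate 2 matched it with a squared distance of 2.03 times sampling variance (bootstrap interval 1.93 to 2.13), while the best blend for any other library left 5.71 times or more. Merging the reads of both libraries predicts a ratio of at most 1, which argues against merged reads. An independent culture in an intermediate state is argued against by the scatter around the blend, a coefficient of variation of 2.51% (2.35 to 2.63), below the 6.45% between control replicates 2 and 3, if cultures vary as that pair did. A candidate explanation is mixing of RNA or cells of both replicates before library preparation. The linear share of replicate 1 was 0.47 from 101 genes at least 4-fold higher in it and 0.49 from 12 genes at least 4-fold lower. Their difference was -0.01 before rounding (-0.04 to 0.00). A blend fitted to the same genes on the log scale gives linear shares of 0.50 and 0.84, a difference of -0.34.

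The median of the stress response list was high in knockdown replicates 1 and 3 and near control in replicate 2, at 0.10 log2 units. Its members were split in replicate 2. Of the 36 members, 17 lay above every control in all 3 knockdown libraries. Over all tested genes the groups did not overlap for 22.5%, in either direction. ASNS, by contrast, was at 21.5 CPM in replicate 2, below the 27.3 to 31.7 CPM of the controls. After removing the trend on GC content and transcript length, the list's median in replicate 1 was 1.57 (1.30 to 1.76), against 1.47 before, which argues against such a bias. Reads of another cell type may contribute and are not excluded: genes of 4 other cell types summed to 60.8 CPM more in replicate 1 than in the control mean, mainly FBN1 and ROBO4, which the controls held at 67.6 and 62.1 CPM. The strength of the knockdown in each library stays open because SNHG14 was not analysed here, and UBE3A differed by 0.10 log2 units between replicates 1 and 2. If replicate 3 is such a mixture, none of its values is a separate observation, those of FOSB and cholesterol synthesis included, and n = 3 overstates the knockdown group in every test.

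Cholesterol synthesis genes were low in all 3 knockdown libraries, including replicate 2, where the stress response median was 0.10. After removing the trend on GC content and length the list's median was -0.71 (-0.74 to -0.57), against -0.73 before, so such a bias is argued against. The list's mean difference was -0.75 in the real grouping, 1 of 10 splits as large, and the highest size in another split was 0.47; 10 splits are too few for a share under 0.05. Without replicate 3 camera still called the list lower with the preset correlation (median -0.71, adjusted p = 6.23e-12; range over alternatives 1.59e-12 to 0.615). An effect of the depletion was not tested, since SNHG14 was not analysed here.

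For the number of genes changed, the real grouping gave 1 and the highest of the other splits 0 (1 of 10 splits as large), too few splits for a share under 0.05. For lists called by camera with the preset correlation, the real grouping gave 7 and the highest other split 14. As many or more came from 8 of the 10 splits, the real grouping included. The number of lists called thus did not set the real grouping apart from other splits, and 10 splits cannot give a share under 0.05. The split with 14 put control replicate 1 with knockdown replicates 1 and 3, which points to a structure of the libraries beyond the groups.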
